A study of Mus musculus with 9 samples.

How the data were processed

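ATAC-seq was made from sorted peritoneal macrophages of 9 mouse samples in 3 groups of 3. Per the labels' protocols, nuclei were treated with Tn5 transposase and libraries were amplified by PCR and sequenced on a HiSeq instrument. Reads were aligned with Bowtie2 2.2.9 to mm10 (GRCm38), per the submitters' processing notes. The peak caller, any shift of reads for the transposase, the handling of duplicates and mitochondrial reads, and the way replicates were merged are not given in the sources used here, and each can change how many peaks a list holds. The labels credit 1 merged list to all 3 samples of a group. RNA-seq, which the series design also names, was not analysed here.

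Each deposited list gives a chromosome, start, end, name and, for each peak, a p-value as the authors deposited it, with no read counts, heights or summits. These p-values reach a floor of 1e-12, taken by 18.5% of monocyte-derived, 19.9% of converted and 12.9% of resident peaks, and peak edges lie on a grid of 25 bp. The names of the lists carry a p-value of 1e-05, yet 5476 resident peaks (22.5%) and 1267 monocyte-derived peaks (3.76%) lie above it, and 0 converted peaks do. Whether the lists were made at a common threshold is not given in the sources used here. P-values were used only to rank or filter peaks within a list. Because depth is unknown, a region missing from a list may be closed or may be below detection.

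Peaks on chromosomes 1 to 19 and X, which are all that the lists hold, were used. Peaks that overlapped by at least 1 bp were merged to regions, and a list calls a region if one of its peaks lies in it. For overlap between lists each was reduced to the 15552 peaks of smallest p-value, ties going to wider peaks, and chance was measured with 100 circular shifts within chromosomes. Gene positions came from a RefSeq table of GRCm38.p6, the build of the lists, with 21631 protein-coding genes and no strand, exons or sequence. Promoter shares planned beforehand were therefore replaced by the share within 1 kb of either gene end, exonic and intronic positions are not stated, and the planned comparison of 26 motifs was not run. Merging was done in Python rather than bedtools.

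For each gene, regions in the gene body and 10 kb on each side were counted, and the net is the number called in the first list only minus the number called in the second only. A region can count for several genes. Nets were summed over 21 gene lists of 391 different genes, 390 of them found (Tpsab1 was not), and set against 10000 random lists of the same size, matched on region number in 10 bins. The percentile describes these lists and is not a test between groups, since genes are not replicates. The lists covered large peritoneal macrophage genes, monocyte and small peritoneal macrophage genes, MHC class II, alternative activation, retinoids, macrophage core genes, identity factors of other tissues, inflammatory mediators, complement and efferocytosis, lipid handling, fatty acid oxidation, cell cycle, integrins and adhesion, housekeeping, and markers of B, T and NK, dendritic, mast and mesothelial or stromal cells, eosinophils and neutrophils. Groups, gene lists, comparisons and the rule for named genes were fixed before the data were examined. The rule takes 19 fixed genes, the 3 members of each list with the largest net in each comparison, and the 5 genes with the largest net in each direction of each comparison, 136 genes in all, not every one of which is reported here; other list members are named only where they have no region or bear on a list's identity.

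Shares have Wilson and differences Newcombe intervals at 95%, in the paired form for overlaps of the same converted peaks. The methods were tested on simulated data: for resident against monocyte-derived, all 7 classes of 10201 simulated regions were recovered exactly. All 10 of 10 planted lists of 20 genes, among 21631 genes, were found, and 1 of 10 unplanted lists lay outside its range. Every region of a planted gene was made resident-only, the largest effect possible, so the power to find smaller differences was not tested. Alternatives were stricter p-values, equal lengths, all peaks, overlap of at least 50% of the shorter peak, distal peaks, other gene windows and, added later, p at most 1e-05 in every list, merging within 200 bp, removal of dense windows, and random regions matched on gene ends. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.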

Results

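Accessible chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in peritoneal macrophages that had been purified by fluorescence-activated sorting from mice. The 9 samples fall into 3 groups of 3. Monocyte-derived macrophages came from mice given 2 ml of thioglycollate, an irritant that draws monocytes into the peritoneal cavity, and were harvested on day 4. Tissue-converted macrophages came from mice given 2 ml of thioglycollate and kept on a tamoxifen diet for 8 weeks. For tissue-resident macrophages the labels give no treatment of their own. Treatment thus differs along with cell origin in every comparison, and the design cannot tell them apart. Every mouse received complexes of IL-4 (5 µg, with 25 µg of antibody to IL-4) every other day from 4 days before harvest, a stimulus for alternative activation. The mice carried a tamoxifen-inducible Cre recombinase at Cx3cr1 and a tdTomato reporter at Rosa26, a combination that lets cells with past Cx3cr1 activity be traced. The files hold 1 merged peak list per group, so no value below has a spread between replicates, sequencing depth is unknown, and no p-value between groups can be given. Intervals are 95% Wilson or Newcombe intervals, which cover counting error over peaks only.

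The monocyte-derived list was the longest and the most distal. It held 33694 peaks covering 6.32 Mb, against 24348 peaks and 3.64 Mb in the resident list and 15552 peaks and 2.46 Mb in the converted list. Median peak width was 150 bp in monocyte-derived and 125 bp in both tissue lists. Peaks lay within 1 kb of an end of a protein-coding gene in 39.1% of the monocyte-derived list (38.6 to 39.7%), 47.7% of the resident list (47.0 to 48.3%) and 53.3% of the converted list (52.5 to 54.1%). List length and position went together. With every list at the length of the converted one, the shares were 46.4% for monocyte-derived and 50.0% for resident. Gene ends stand in for promoters because strand was not part of the annotation used.

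Merging overlapping peaks gave 36843 regions, of which 10356 (28.1%) were called in all 3 lists. These shared regions were mostly near genes, with 58.3% within 1 kb of a gene end. Monocyte-derived-only regions were the largest class, at 14557 (39.5%), and 24.4% of them lay near a gene end. The monocyte-derived and resident lists shared 5289 further regions, monocyte-derived and converted 1312, and converted and resident 715. Resident-only regions numbered 4044 and converted-only regions 570. The 715 regions of both tissue lists were as distal as the monocyte-derived-only class, at 23.2% near a gene end (20.3 to 26.4%). Among those with the smallest p-values in both lists were a 350 bp region in S1pr1, the sphingosine-1-phosphate receptor gene (chromosome 3, 115714789 to 115715138), and regions in Kif26b, Nova1, Fmn1, Cth and Plxna2. These were picked by rank after the lists had been examined.

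**Figure D1:**
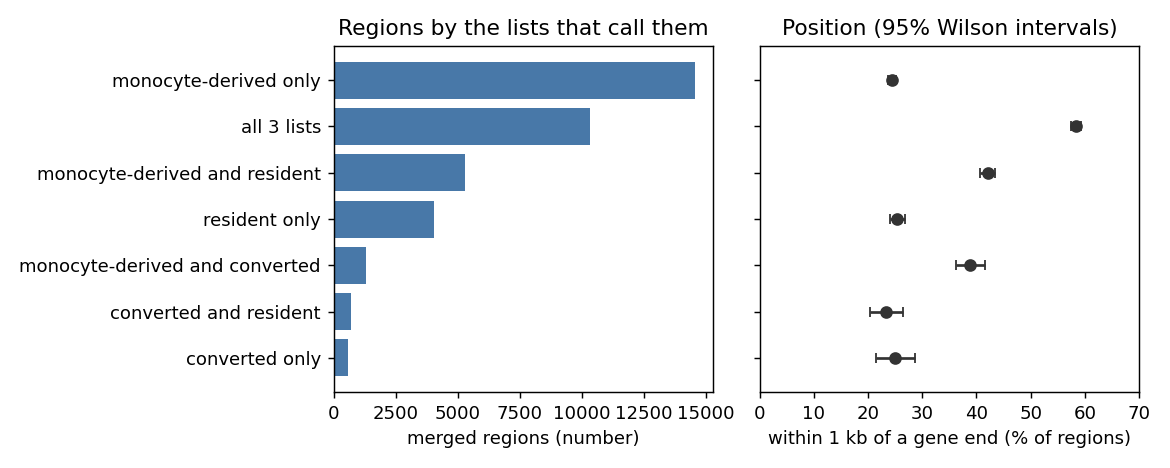
Left, the number of merged regions in each class of lists that call them; right, the percent of each class within 1 kb of a protein-coding gene end, with 95% Wilson intervals. The 10356 regions of all 3 lists stand at 58.3%, while single-list classes lie near 25%.

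The series title speaks of a conversion of alternatively activated macrophages, so the first question was which other population the converted cells resembled. Their open chromatin was largely shared with both. Of the 15552 converted peaks, 79.1% (78.4 to 79.7%) overlapped peaks of both other lists, 11.6% of the monocyte-derived list only, 5.48% of the resident list only, and 3.84% of neither. At equal list lengths, 65.1% of converted peaks overlapped the monocyte-derived list and 61.3% the resident list, a resident minus monocyte-derived difference of -3.86 percentage points (-4.78 to -2.95). Circular shifts of the lists gave at most 0.341% overlap for either. Among distal peaks at equal lengths the difference was 0.0138 points (-1.43 to 1.46). With only peaks of p at most 1e-10 it turned to 17.2 points at equal lengths and stood at -12.3 points without them.

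The regions on which the other groups disagree gave the opposite side. Of 4759 regions in the resident but not the monocyte-derived list, 715 (15.02%, 14.0 to 16.1%) were also called in converted cells. Of 15869 regions in the monocyte-derived but not the resident list, 1312 (8.27%, 7.85 to 8.71%) were. The difference was 6.76 percentage points (5.68 to 7.88). Among regions at the p-value floor of 1e-12 in the resident or monocyte-derived list, respectively, the shares were 67.3% (37 of 55) and 28.0% (101 of 361). Restricting every list to p at most 1e-5 turned the direction, to 13.8% of resident-only against 17.2% of monocyte-only regions, a difference of -3.47 points (-4.63 to -2.25). Neither population was the nearer one under all settings.

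**Figure D2:**
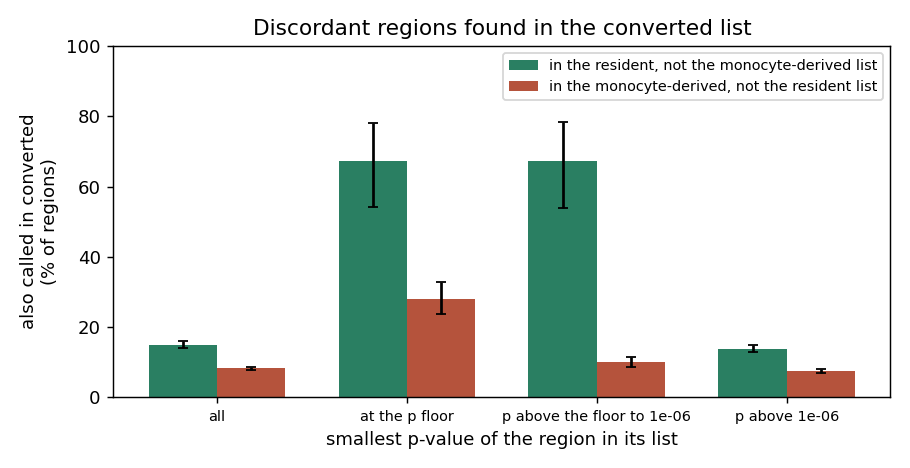
Percent of regions also called in the converted list, for regions of the resident but not the monocyte-derived list and the converse, by the region's smallest p-value in the resident or the monocyte-derived list, respectively; error bars are 95% Wilson intervals. Resident regions are higher in every class, from 13.8% against 7.52% for the weakest to 67.3% against 28.0% at the p-value floor.

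Genes of monocytes and small peritoneal macrophages had fewer regions in resident than in monocyte-derived cells. Counting regions in each gene body and 10 kb on each side, this list held 33 regions in the monocyte-derived list and 11 in the resident list, a net of -22 that lay below the central range of 10000 random lists matched on region number (-16 to -1; percentile 0.015). No member of its 24 genes had more resident regions and 12 had fewer. Such counts were not particular to this list. Of 18 housekeeping genes, whose net lay inside its range, none had more and 10 had fewer. Ifitm6 had 3 monocyte-derived and 0 resident regions, Lyz1, a lysozyme gene, 5 and 1, and Cx3cr1, the fractalkine receptor gene, 2 and 0. At equal list lengths Lyz1 had 2 and 0, while Ifitm6 and Cx3cr1 had no region. Ccr2, the monocyte chemokine receptor gene, had none in any list.

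Inflammatory mediators, lipid handling, dendritic cell markers and B cell markers also lay below their random ranges. Inflammatory mediators had a net of -33 (percentile 0.485), with 16 of 22 genes lower in resident cells, against 10 of 18 housekeeping genes. Il10, an anti-inflammatory cytokine gene, had 5 monocyte-derived and 0 resident regions, and the neutrophil chemoattractant genes Cxcl1 and Cxcl2, whose windows overlap, had 6 each against 1 and 0. Lipid handling had a net of -33 (percentile 2.13), with Abca1, a cholesterol exporter, at 7 and 3, the scavenger receptor gene Cd36 at 7 and 3, and Apoc2 at 4 and 0. At equal list lengths Cd36 had 6 and 2, Abca1 2 and 1, and Apoc2 no region. The dendritic cell list had a net of -30 (percentile 1.73), with Bcl11a at 9 and 1 and Tcf4 at 13 and 7. The B cell list had a net of -19 (percentile 1.52), of which Bach2 gave 19 against 6 regions. Of its 16 members 9 had a region in some list, among them Fcrla (4 and 1), Blnk (4 and 3) and Cr2 (3 and 3). Ms4a1 and Pax5, which mark B cells, had no region in any list. At equal list lengths only the monocyte list and the dendritic cell list stayed below their ranges. The same held by nearest gene end, where each region counts for 1 gene only. There the inflammatory, lipid and B cell lists lay inside. With 50 kb on each side only the lipid and B cell lists stayed below, and at p at most 1e-10 none of the 5. About 5% of 21 lists would lie outside by chance.

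Large peritoneal macrophage genes lay at the upper edge of their range in resident cells. Their net was -11, against a random mean of -26.8 (percentile 97.47), with 8 of 27 genes higher in resident and 13 lower. Settings moved this list from above its range (percentile 99.02 at p at most 1e-5) to percentile 57.0 by nearest gene end and 2.25 at p at most 1e-10. Gata6, the transcription factor gene of resident peritoneal macrophages, had 1 resident and 0 monocyte-derived regions. Icam2 and Timd4, which encode surface molecules of large peritoneal macrophages, had 1 and 0 each, and Adgre1, which encodes F4/80, had 4 and 1. Garnl3 had 6 and 2, while Rarb, a retinoic acid receptor gene, had 5 and 7. At equal list lengths Gata6 had 0 and 0, Icam2 and Timd4 1 and 0 each, and Adgre1 2 and 0. There Garnl3 had 4 and 2 and Rarb 4 and 4. From other lists, Marco, a scavenger receptor gene, had 2 and 0. Padi4, a peptidylarginine deiminase gene of neutrophils, had 3 and 0.

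In the main setting the other lists lay inside their ranges, and values below are from it unless stated. At p at most 1e-10 alternative activation and retinoid genes lay below. With 50 kb on each side MHC class II, alternative activation, macrophage core, and T and NK genes did. By nearest gene end macrophage core genes did. Against random regions matched on gene ends MHC class II, alternative activation and macrophage core genes did. Antigen presentation by MHC class II had a net of -24 (percentile 5.42), with Cd86, a costimulatory ligand gene, at 10 monocyte-derived and 4 resident regions, H2-DMa at 9 and 3, and Cd74, the invariant chain gene, at 6 and 3. At equal list lengths Cd86 had 4 and 2, H2-DMa 2 and 2, and Cd74 1 and 1. Alternative activation genes had a net of -50 (percentile 8.38). There, Arg1, the arginase gene induced by IL-4, had 8 and 3 regions, Mrc1, the mannose receptor gene, 3 and 2, and Pdcd1lg2, which encodes PD-L2, 2 and 0. Retnla had 1 and 2, Chil3 1 and 1, and Irf4 1 and 1. Ucp1, an uncoupling protein gene, had 0 and 2 regions. At equal list lengths Arg1 had 4 and 2, Mrc1 1 and 1, Retnla 1 and 0, Ucp1 0 and 1, and Pdcd1lg2 no region. By nearest gene end Arg1 had 4 and 4. The retinoid list stood at percentile 25.6, with Dhrs3, a retinaldehyde reductase gene, at 13 and 6 and Aldh1a2 at none. Macrophage core genes stood at 5.88 (Spi1, the PU.1 gene, 3 and 1; Csf1r 2 and 2), identity factors of other tissues at 9.53 (Mef2c 17 and 8), and complement and efferocytosis at 20.4 (Cd163 4 and 0; Itgb5 7 and 0). Fatty acid oxidation stood at 94.9, cell cycle at 65.2 (Myc 6 and 1), integrins and adhesion at 86.3 (Itgb2 8 and 3) and housekeeping at 75.5 (Actb 5 and 3). The remaining markers of other cells stood at 2.15 for T and NK cells, 31.4 for eosinophils, 77.4 for neutrophils, 25.3 for mast cells and 82.5 for mesothelial and stromal cells. The T and NK net of -8 equalled the lower bound of its range (-8 to 2), which counts as inside. With 50 kb on each side that list lay below in both comparisons against monocyte-derived.

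**Figure D3:**
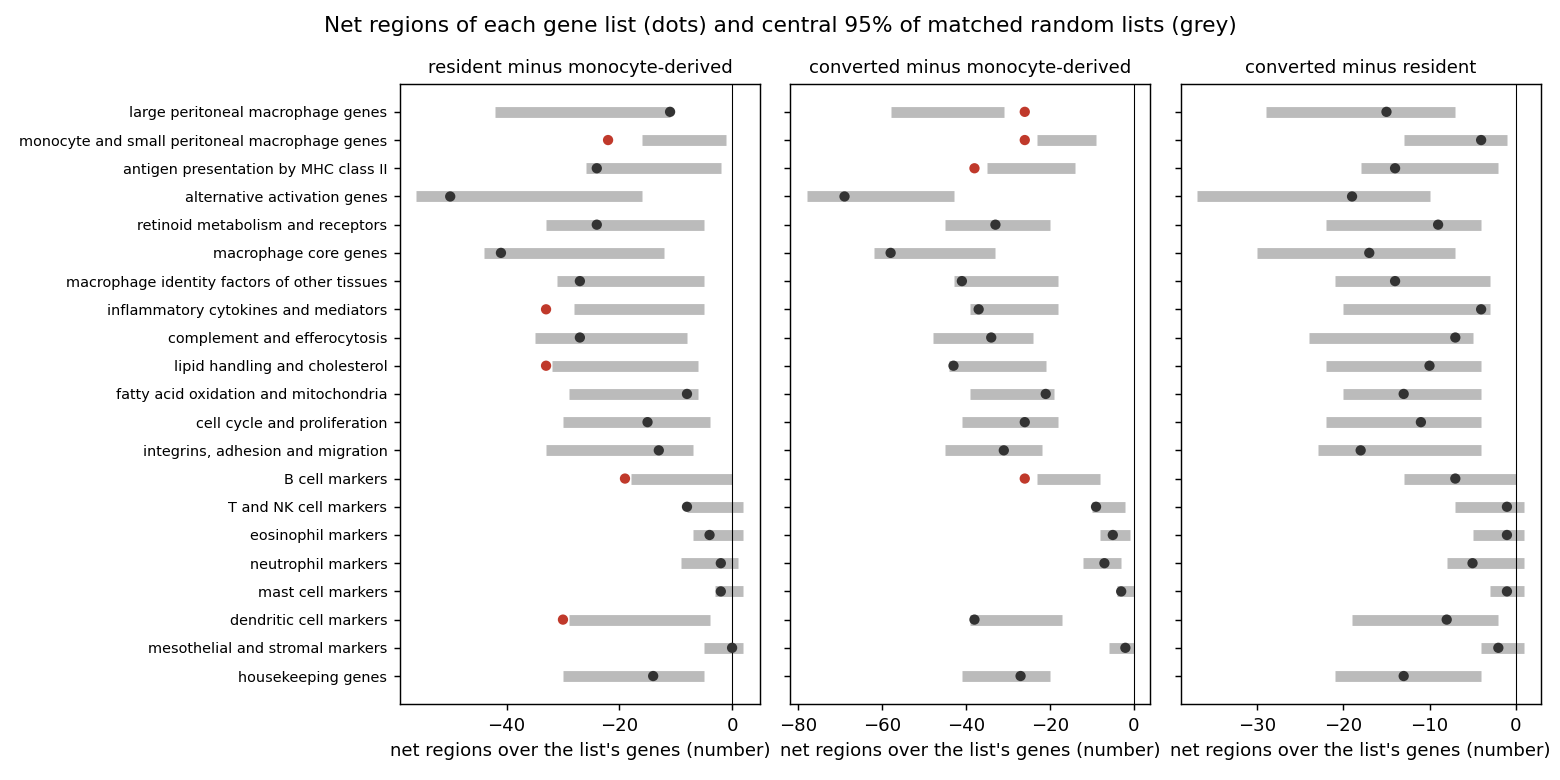
Net regions over each of the 21 gene lists (dots, red outside the range) in each comparison, with the central 95% of 10000 matched random lists in grey. In the converted minus resident panel every dot lies inside the grey bar.

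Large peritoneal macrophage genes lay above their random range in converted cells. Their net against monocyte-derived was -26, where random lists averaged -43.7 (-58 to -31; percentile 99.7). Tgfb2, which encodes a transforming growth factor, had 4 converted and 0 monocyte-derived regions, Gata6 2 and 0, and Garnl3 3 and 2. These were the 3 of 27 genes with more converted regions, while 17 had fewer, among them Rarb (3 against 7), F10, the coagulation factor X gene (2 against 6), and Prg4 (0 against 4). In contrast, monocyte and small peritoneal macrophage genes had a net of -26 (percentile 0.0900), with 16 of 24 lower in converted and none higher. Cx3cr1 had no converted region, and Lyz1 had 1 against 5. MHC class II genes had a net of -38 (percentile 1.34), with 12 of 14 lower and Cd74 at 0 converted against 6 monocyte-derived regions, Cd86 at 1 against 10 and H2-Ab1 at 0 against 3. B cell markers had a net of -26 (percentile 0.910), again mainly from Bach2 at 3 against 19. At equal list lengths none of these 4 lists stayed outside its range. There Cd74 had 0 converted against 1 monocyte-derived region, Cd86 1 against 4, H2-Ab1 0 against 1 and H2-DMa 3 against 2. Lower converted counts were general in the main setting. Among lists inside their ranges, 14 of 18 housekeeping genes and 21 of 22 macrophage core genes were lower, and none higher. Across all genes, Irs1, an insulin receptor substrate gene (4 converted against 1), Hspa5, which encodes the chaperone BiP (4 against 1), Fer and Tspan9 were among the largest gains. Zmiz1 (0 against 22) and Vps13d (8 against 31, in a window that holds Dhrs3) were among the largest losses.

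Against resident cells, the nets of converted cells lay inside the random range for all 21 lists in the main setting. Elsewhere, dendritic cell markers lay above it at equal list lengths (net 8, percentile 98.8) and in the 50% of smallest p-values (98.6), where neutrophil markers lay below (1.01). Identity factors of other tissues lay below by nearest gene end (1.25). The nearest to an edge was the inflammatory list, with a net of -4 (percentile 96.1). Monocyte genes had a net of -4, MHC class II genes -14 and large peritoneal macrophage genes -15, with percentiles of 84.2, 11.7 and 61.1. Single genes had unequal counts. Tgfb2 had 4 converted and 2 resident regions, Hspa5 4 and 1, Eif4e 4 and 1, and Arid5b 5 and 2. With peaks within 200 bp merged Tgfb2 had 2 and 2, and in the 50% of smallest p-values Tgfb2 and Eif4e each had 0 and 1. Adgre1 had 0 converted and 4 resident regions, Cd74 0 and 3, Mrc1 0 and 2, Padi4 0 and 3, and Zmiz1 0 and 8. With 15552 converted against 24348 resident peaks, a missing converted region is not evidence that the site was closed, since depth is unknown.

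At Gata6 (chromosome 18, 11052510 to 11085636, GRCm38) both tissue lists had calls that lay within 1 kb of the same gene end but did not overlap. The converted regions were 11052289 to 11052413, 0.1 kb outside the gene, and 11052439 to 11052538, across that end. The resident region was 11053264 to 11053338 inside the gene. The authors' peak-caller values for them, 4.87e-06, 5.61e-06 and 8.27e-06, were weaker than the medians of their lists. With each region given to its nearest gene end alone the Gata6 counts became 7 monocyte-derived, 2 converted and 4 resident. In Tgfb2 (chromosome 1, 186622787 to 186709697) 1 region, 186705514 to 186705613, was shared by both tissue lists, and none of the 5 regions was in the monocyte-derived list. Ucp1 held a region of both tissue lists inside the gene (chromosome 8, 83291964 to 83292138). Around Arg1 (chromosome 10, 24915207 to 24927470) 2 regions were called in all 3 lists, at 24930164 to 24930563 and 24931564 to 24931763, both outside genes. Of the other 6, 5 were monocyte-derived only, among them 24911264 to 24911588 at the p-value floor inside a neighbouring gene. At Irf4, the transcription factor gene of alternative activation, 1 region at the gene end (chromosome 13, 30749064 to 30749338) was in all 3 lists.

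**Figure D4:**
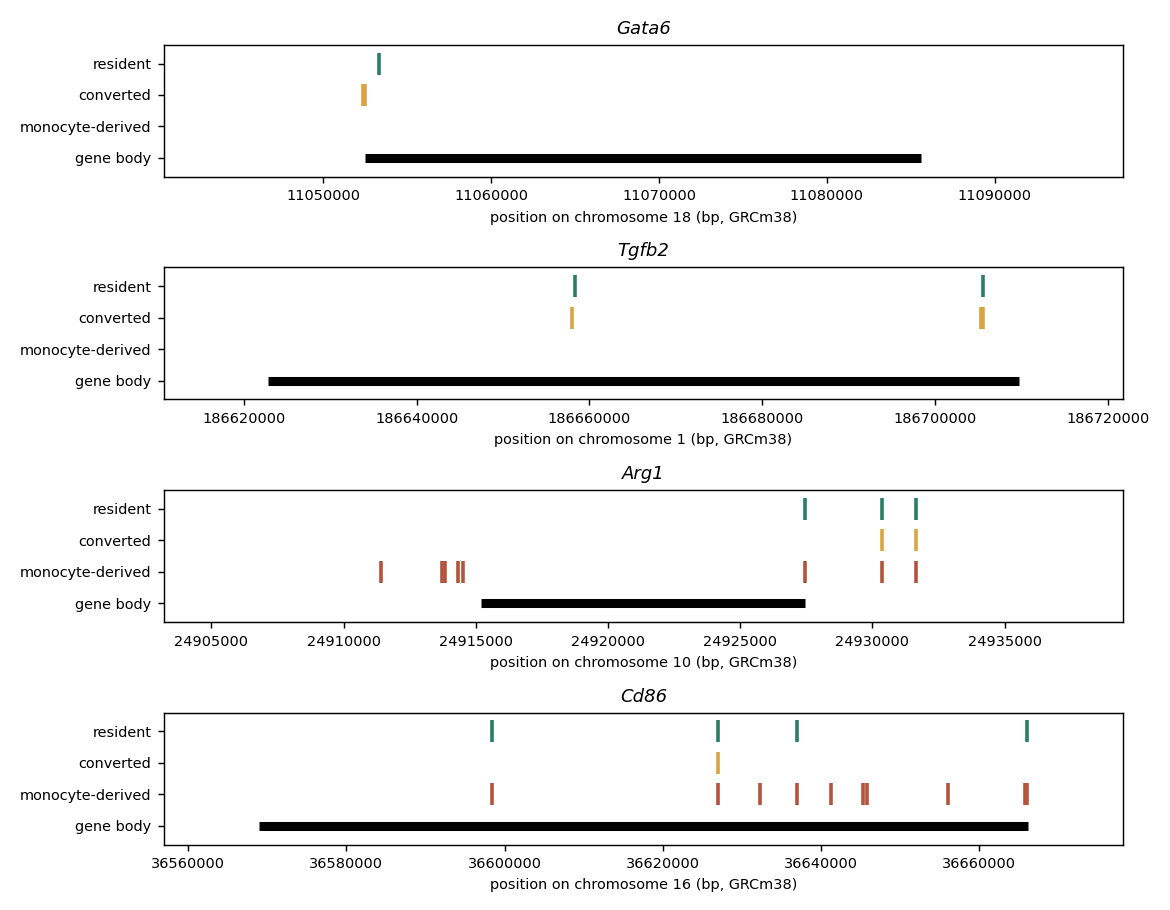
Called regions (vertical marks, at region centres) in each list around Gata6, Tgfb2, Arg1 and Cd86, with the gene body in black and GRCm38 positions in bp on the x axis. Gata6 and Tgfb2 have no monocyte-derived mark, while Arg1 has 8 and Cd86 has 10. With regions given to the nearest gene end alone, Arg1 has 4 monocyte-derived and 4 resident regions. Gata6 then has 7 monocyte-derived, 2 converted and 4 resident regions, and Tgfb2 has 1, 5 and 4.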

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

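Settings added after seeing the data were p at most 1e-5 in every list, merging within 200 bp, windows without dense loci, random regions matched on gene ends, and p at most 1e-10 without equal lengths. No paired analysis was possible because each group has 1 merged list, which carries no replicate number; leaving out replicates could not be run for the same reason, and the motif comparison was not run. Using every sequence in the files moved nothing, since they hold chromosomes 1 to 19 and X only. Depth is unknown, so it limits every absence of a call.

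By construction, the 50% of each list with the smallest p-values held 16847 monocyte-derived, 7776 converted and 12174 resident peaks, and p at most 1e-10 left 6236, 3093 and 3134. Shares near gene ends were 45.5%, 59.6% and 52.7% in those upper parts and 62.9%, 72.8% and 71.9% at p at most 1e-10. They were 46.4% for monocyte-derived and 50.0% for resident at equal lengths, and 45.8%, 58.9% and 53.9% within 2.5 kb. Monocyte-derived stayed lowest and converted highest in each.

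The overlap difference of -3.86 points became -6.47 with an overlap of at least 50% of the shorter peak and -6.11 with all peaks. It was 0.0138 among distal peaks, where the cause was not tested, and 17.2 with p at most 1e-10. That last value comes from the equal lengths, which keep only the widest 3093 of 6236 monocyte-derived peaks; without them it was -12.3. The discordant difference of 6.76 points was 3.70 at equal lengths, 3.77 in the upper 50%, 9.01 for distal peaks, 24.2 at p at most 1e-10 and 9.71 with merging within 200 bp. It reversed to -3.47 at p at most 1e-5. Regions of both tissue lists alone numbered 2013 at equal lengths and 160 at p at most 1e-10, against 715.

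Of the gene lists, 5 lay outside their range for resident against monocyte-derived; 2 did in the upper 50%, 2 at p at most 1e-10 (both new), 2 at equal lengths, 7 with 50 kb on each side (2 of the 5 among them, and the monocyte, inflammatory and dendritic lists inside), 3 by nearest gene end, 3 with merging within 200 bp and 8 against random regions matched on gene ends. For converted against monocyte-derived, 4 lay outside. None of these 4 was among the 3 outside in the upper 50%, the 2 at p at most 1e-10 or the 1 at equal lengths, and 3 of the 4 were among the 7 with 50 kb on each side and the 7 against matched regions. For converted against resident, 0 became 2 in the upper 50%, 1 at equal lengths and 1 by nearest gene end. The causes were not tested. At p at most 1e-10 the distance from the random mean reversed to 0.846 for monocyte genes and 1.65 for B cell markers (resident against monocyte-derived), and to -2.37 for large peritoneal macrophage genes and 1.83 for B cell markers (converted against monocyte-derived). By nearest gene end it was -1.33 for large peritoneal macrophage genes. Among the 136 named genes, equal lengths changed the sign of 8 of 116 nonzero nets for resident against monocyte-derived (Retnla and Spi1 among them), 15 of 122 for converted against monocyte-derived and 5 of 105 for converted against resident; a further 26, 33 and 28 fell to 0. At p at most 1e-10 only 40, 48 and 9 kept their sign.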

Other observations

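The strongest monocyte-derived-only regions lay near Mapre2, in Tnfrsf8, which encodes CD30, and 42.4 kb from Bhlhe40, a transcription factor gene. Strong regions shared by monocyte-derived and converted cells alone lay in Ifi207, an interferon-inducible gene, in Meis1 and in C3ar1, the receptor gene for complement C3a. Pkm, the pyruvate kinase gene, held a strong region of monocyte-derived and resident cells that was not called in the converted list. The widest region of all 3 lists, 3300 bp on chromosome 17 (39843089 to 39846388), lay at Rn18s-rs5, a ribosomal RNA-like pseudogene.

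The tests below that were chosen after the result was seen are those of list length, of p-values in the discordant regions, of background at multi-copy loci and of B cells. Converted cells held 15.02% of resident-only and 8.27% of monocyte-only regions. Equal list lengths left a difference of 3.70 points (2.21 to 5.19). That cut kept monocyte-derived peaks only up to a p-value of 3.02e-06, against 8.27e-06 for resident and 9.72e-06 for converted. Regions of both tissue lists alone rose from 715 to 2013 under it. The cut can thus itself add such regions, so length stays open as a cause of the difference. With p at most 1e-5 in every list it was -3.47 points, yet the equal-length lists also hold 0 peaks above 1e-5; these disagree, so looser resident p-values stay open. At the p-value floor, removing windows of 100 kb with 15 or more regions left 45.3 points (30.3 to 56.8). The difference was thus also present outside those windows. The removal kept 46 of the 55 resident-only regions, so it could hardly have brought the difference to 0. It therefore cannot decide on dense calling. Call density does not measure repeated sequence, so multi-copy loci stay open. Shifts of the converted list reached at most 1.82% overlap with the 55 resident-only regions, against 67.3% observed. Random placement thus does not give that overlap. Every pair of lists overlapped at least 168 times more than shifts gave, so shifts cannot decide the difference from 28.0%. A shared tissue environment stays open as an untested explanation, as does unequal depth. Treatment and its timing cannot be told apart from cell origin here.

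Resident cells exceeded monocyte-derived cells most at Sfi1 (140 against 105 regions), Gm38510 (17 and 1), Tmem267 (18 and 3), C130026I21Rik (13 and 1) and Gm51877 (17 and 8), some of which share windows. With p at most 1e-5 in every list their summed excess was 60, against 87. These genes were picked for their excess, and only 22.5% of resident peaks lay above 1e-5, so a fall to 0 was unlikely beforehand. The value shows only that peaks above 1e-5 did not make up all of the excess, and looser p-values otherwise stay open. Merging peaks within 200 bp reduced the summed excess to 39, with Sfi1 at 41 against 38 and Gm51877 at 5 against 4. Most of the excess at Sfi1 and Gm51877 thus depended on counting peaks within 200 bp separately. Whether these are split peaks or distinct sites was not tested. Without merging, p at most 1e-5 gave Sfi1 118 against 102. At p at most 1e-10 the summed excess was 4. These windows held a median of 21.1 regions per 100 kb, against 2.43 over all genes, which may point to reads from repeated sequence; with no sequence used here, background and open chromatin cannot be told apart at these genes. No biological explanation was tested.

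In the main setting, more gene lists lay outside their ranges than in most shuffles of the region classes. With 1000 random lists each, 8 of the 63 lists by comparisons lay outside; when region classes were shuffled 99 times, as many did so in 2 of 100 arrangements, the real one included, with 9 as the highest other and a mean of 2.86. The shuffle bears only on calls scattered over genes by chance. At equal lengths and at p at most 1e-10 only 4 of 63 lay outside, and no shuffle was run there. For the B cell list, carry-over of B cells into the monocyte-derived sort is a possible explanation. Without Bach2, which macrophages can also express, the list stood at percentile 58.3 among random lists, so its position rests on 1 gene; weak B cell signal may still be below detection and cannot be told apart from none. Biological difference between the groups stays open as an untested explanation.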
